A study of Mus musculus with 144 samples.

How the data were processed

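Per the labels, cross-linked chromatin of mouse cells was sonicated, immunoprecipitated with an antibody to each target and sequenced. The submitters' processing notes name bcl2fastq 2.17.1.14, Bowtie2, the peak caller MACS 1.4.2-157 and genome build mm10, and the steps between them, the settings and the control libraries are not given in the sources used here. Input libraries were not used here. Of 152 deposited files, 85 hold promoter matrices of the histone marks and 67 hold peak lists.

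The deposited matrices give the read coverage of 94610 transcript starts in 20 bins of 50 bp (500 bp to each side), as coverage summed over the bases of a bin by the authors, with no scaling to library depth. This was tested on the values: 55 of 160837000 were not whole numbers (no tolerance), and where lone reads cover neighbouring bins the commonest sum in a library was near a read length, though not the only one. Of the windows, 88171 were distinct, since 6.81% of transcripts share a window with another. In 11 libraries the highest bin was above 50000, a level set after the values were seen, which is read here as no ceiling from duplicate removal. These 11 were H3K27ac on days 1 and 2, H3K27me3 in MEFs and on days 1 and 2, H3K4me1 on days 1, 2, 4, 5 and 7, and H3K4me3 on day 1. The score in the fifth column of the deposited peak lists is, per the labels and the values, the MACS score of each peak (on a log10 p scale, from 50 up), made by the authors for each library's own list and not scaled between lists. Coverage is not a count of reads, so no counting interval is given, and depth is stated as mean reads covering each base of the windows.

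Groups were taken from the labels: target, genotype (Mbd3f/-, Gatad2a-/-, WT, V6.5 ES cells) and stage (MEF, days 1 to 8, iPS, ES). Libraries named as re-analysed from an earlier series were kept with that origin. The H3K4me3 iPS values pool 2 libraries, and the label H3K27me3 MEF 2 names the values of the other H3K27me3 MEF sample, which were used once. ES cells are V6.5 wild type by their source name and Mbd3f/- by their cell line tag, and were taken as V6.5. The source name of the Gatad2a-/- MEF sample calls it post induction, and it was taken as MEF by its title.

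For promoters, the mean over bins was quantile normalized between the libraries of a mark, a pseudocount of the median positive value divided by 4 was added, and windows in the lowest 25% were left out. Trends (log2 per day) were fitted in limma 3.58.1 (lmFit, eBayes with trend) under R 4.3.3 with the package data.table (1.17.8), on days 1 to 8 of Mbd3f/- cells, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. With 1 library per day the spread around the line is the error. Genotypes were compared at matched stages with the stage as a block, and the trends of Gatad2a-/- and Mbd3f/- cells by an interaction of genotype and day. No paired analysis was possible because no samples are paired beyond the stage used as the block. Each trend was refitted in 100 random orders of the days, and each genotype comparison in the other splits of its libraries. Splits that keep 1 library of each stage in each group were added after the data were seen. The fits were tested on simulated data with 200 changed windows at known slopes or differences.

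Likeness to iPS cells was the Spearman correlation across windows with the iPS library of the mark minus that with the MEF library. Peaks of a day were called shared when they overlapped a peak of the iPS list by 1 bp or more. Chance values are means over circular shifts of the peaks. Relations with the day were tested with Pearson's r and Spearman's rho by exact two-sided permutation over all orders of the days, with Benjamini-Hochberg adjustment over 7 likeness relations, 15 peak relations, 2 region relations and 118 relations of list genes with a peak. The smallest exact p that 8 days allow is 5.0e-05. Overlaps, permutations and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

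For genes, peaks were joined to 21883 protein-coding RefSeq genes of mm10 extended by 10 kb to either side. The covered length per gene, as a share of the list's total, was tested for a trend by exact permutation of Spearman's rho, for genes with a peak on 3 or more days. Random lists of the same size, matched on mean covered length, were drawn 10000 times. This measure was set after the files were read and before its own outcomes were seen. The plan had joined peaks to transcript starts and tested the lists with camera and fry on the promoter fits. The matrices name windows by Ensembl transcript, windows were not paired with gene symbols here, and camera and fry were not run.

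The 21 gene lists were fixed before the data were examined: naive pluripotency, fibroblast and mesenchymal, epithelial, immediate early, Hox, lineage transcription factor, ribosome biogenesis, cell cycle, cell cycle inhibitor, germline, 2-cell stage, imprinted and NuRD complex genes, ribosomal protein and olfactory receptor genes as controls, and markers of keratinocytes, neurons and glia, blood, endothelium, extraembryonic cells, and muscle and fat. All matched in full except imprinted genes (18 of 21). Named genes follow a rule fixed then for promoters and carried over to covered length: up to 4 list members past the threshold with the smallest p (ties by name), the 10 largest changes each way, Mbd3 and Gatad2a, and up to 8 members of the naive and of the fibroblast list per factor. Ranking these 8 by score, and naming no member of lists in which none passed, departs from the rule or was added to it. The 10 largest changes are named for H3K27ac covered length, and promoter windows for H3K27ac only, the largest each way. Esrrb, Nanog, Pou5f1, Klf4, Col1a1 and Cldn4 under H3K27ac were chosen outside the rule, after their values were seen. Some genes that the rule selects are not reported here.

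Alternatives fixed before the data were examined were median centring, no rescaling, other pseudocounts and filters, the highest bin, the MEF library as day 0, a step in place of a line, no stage block, a score of 100 or more, a stricter overlap, other likeness measures, and each day or stage left out. Alternatives chosen after seeing the data were the libraries without a duplicate ceiling left out, libraries of 62-base reads only, peaks resized, an equal number of highest-scoring peaks per day, the same with the iPS list shortened to that number, and all alternatives of the gene measure.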

Results

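Mouse embryonic fibroblasts (MEFs) carrying a doxycycline-inducible cassette of Oct4, Klf4, Sox2 and c-Myc were followed for 8 days of reprogramming toward induced pluripotent stem (iPS) cells. Chromatin immunoprecipitation with sequencing (ChIP-seq) measured the 4 factors, RNA polymerase II (PolII) and 7 histone marks. The time course was done in Mbd3f/- cells, which have a floxed and a deleted allele of Mbd3, a subunit of the NuRD chromatin-remodelling complex. H3K27ac was also measured in Gatad2a-/- cells, which lack another NuRD subunit, and in wild-type (WT) cells. V6.5 embryonic stem (ES) cells served as a pluripotent reference. From day 3 the cells, and the iPS and ES cells, grew on irradiated human foreskin fibroblasts, per the labels. The labels also name inhibitors added during the course, at times that differ between protocols, so early and late days also differ in medium.

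The 144 samples gave 137 sets of values that were used, 1 for each target, genotype and stage, so no value has replicates. The H3K4me3 iPS values pool 2 libraries, per the labels. The Mbd3f/- series held days 1 to 8 for every target except c-Myc, which had days 1 to 7. Oct4 and Sox2 had no MEF library, and H3K9me2 no ES library. H3K27ac had 5 Gatad2a-/- libraries (MEF and days 2, 4, 6 and 8) and 4 WT libraries (MEF, days 4 and 8, iPS). The 4 WT libraries, the Mbd3f/- MEF libraries of H3K27ac and H3K4me3, and the Oct4 iPS library came from an earlier series. So did 1 of the 2 libraries pooled in the H3K4me3 iPS values. The Oct4 iPS library also used another antibody than the time course.

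Depth within the promoter windows ran from 0.203 to 13.04 mean reads covering each base over the 85 histone libraries. It lay between 5.18 and 13.04 for H3K4me3. In Mbd3f/- H3K27ac it was 8.04 on day 1, 3.33 on day 3, 3.67 on day 7, 2.36 on day 8 and 1.35 in iPS cells. For H3K36me3, H3K9me2 and H3K9me3 it stayed between 0.203 and 0.780. Peak lists also differed in shape between days. H3K27ac had 43818 peaks of median width 2322 bp on day 1 and 85348 of 281 bp on day 8. Klf4 had 4838 peaks of 161 bp on day 1 and 38553 of 1125 bp on day 8. Oct4 fell from 15586 to 10797 peaks, Sox2 from 23172 to 10935, and PolII from 60150 to 40305, while c-Myc had 5805 on day 1, 2418 on day 3 and 15674 on day 7.

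H3K27ac, a mark of active promoters and enhancers, was lost from fibroblast regions and gained in pluripotent regions over the 8 days of the Mbd3f/- course. Fibroblast-only regions were the 48529 H3K27ac peaks of the MEF list that overlapped no peak of the iPS or ES list. Of these, 32.4% held an H3K27ac peak on day 1, 18.4% on day 3, 11.7% on day 5 and 6.12% on day 8, where chance placement gave 5.92%. Pluripotent-only regions were the 25977 peaks found in both iPS and ES cells and not in MEFs. Of these, 11.1% held a peak on day 1, 26.3% on day 4, 53.4% on day 5, 83.1% on day 7 and 70.0% on day 8, against chance values of 5.59% on day 1 and 3.00% on day 8.

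The share of fibroblast-only regions fell with the day (r = -0.927, exact two-sided permutation p = 0.000992, adjusted p = 0.00124; rho = -0.952, exact p = 0.00114, adjusted p = 0.00228). Without days 1 and 8, r was -0.876 (exact p = 0.0167). The share of pluripotent-only regions rose (r = 0.937, exact p = 0.00124, adjusted p = 0.00124; rho = 0.905, exact p = 0.00456, adjusted p = 0.00456), and without days 1 and 8 r was 0.957 (exact p = 0.00556). Without days 1 and 2, whose H3K27ac promoter values show no ceiling on duplicate reads, r was -0.910 (exact p = 0.0167) and 0.887 (exact p = 0.0278), and rho for the pluripotent-only share no longer passed (0.771, exact p = 0.103). Both relations form a family of 2 and were added after the data were seen. When every peak was resized to 1000 bp, the pluripotent-only share was 6.75% on day 1, 45.4% on day 7 and 73.6% on day 8. The drop from day 7 to day 8 thus turned into a gain. Resizing narrows most of the 45986 peaks of day 7 (median 2031 bp) and widens most of the 85348 of day 8 (281 bp). The resized shares can therefore follow the number of peaks, and no chance value was computed for them.

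WT cells had a peak in 24.9% of fibroblast-only regions on day 4 and 22.9% on day 8, where Mbd3f/- cells had 20.9% and 6.12%. In pluripotent-only regions WT cells had a peak in 16.7% on day 4, 28.5% on day 8 and 80.0% as iPS cells, where Mbd3f/- cells had 26.3% on day 4 and 70.0% on day 8. With every peak resized to 1000 bp these were 8.53%, 13.7% and 59.5% in WT cells, and 15.95% and 73.6% in Mbd3f/- cells. In fibroblast-only regions the resized shares were 22.7% and 21.1% in WT cells and 19.2% and 6.70% in Mbd3f/- cells on days 4 and 8. WT MEFs had a peak in 61.8% of fibroblast-only and 4.60% of pluripotent-only regions. The regions were drawn on Mbd3f/- lists, which sets the Mbd3f/- MEF and iPS values to 100% or 0%. With 1 library per genotype and stage this difference was not tested, and genotype goes with series on days 4 and 8.

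**Figure D1:**
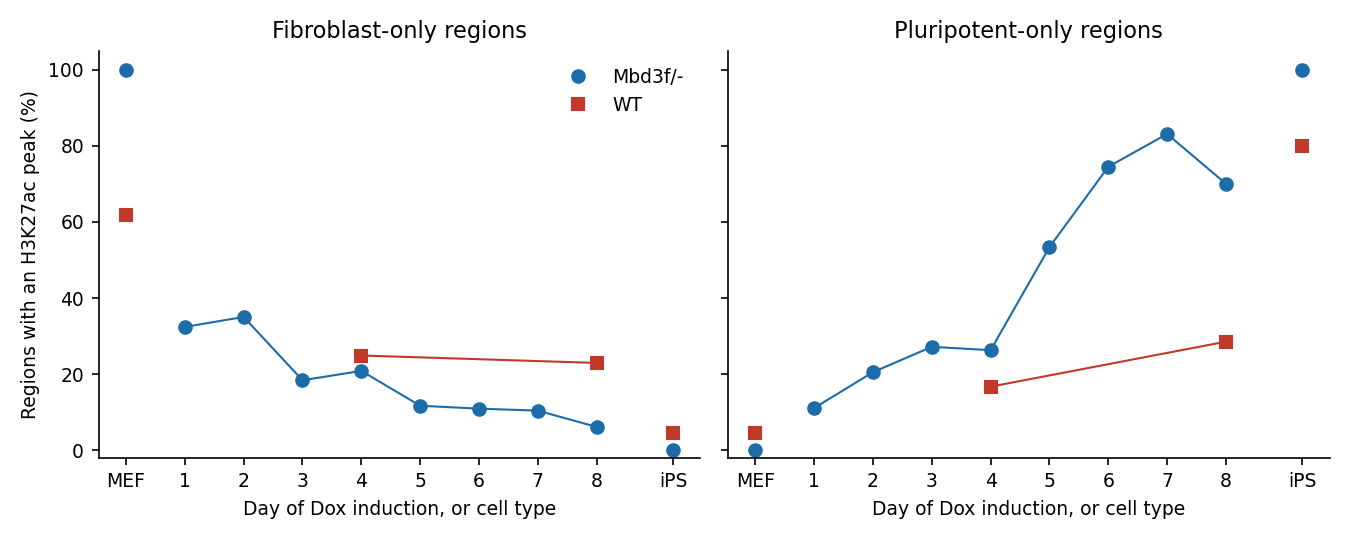
Percent of fibroblast-only (left) and pluripotent-only (right) regions with an H3K27ac peak, by day of doxycycline (Dox) induction or cell type, 1 library per point. Mbd3f/- cells (circles) reached 70.0% of pluripotent-only regions on day 8 and WT cells (squares) 28.5%, while the Mbd3f/- MEF and iPS points are 100% or 0% by the definition of the regions.

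Genes of the naive pluripotency network gained H3K27ac, and fibroblast and mesenchymal genes lost it. The measure was the length covered by H3K27ac peaks over each gene and 10 kb to either side, as a share of the length covered by the whole list, in Mbd3f/- cells on days 1 to 8. Of 30 naive pluripotency genes, 19 rose and 0 fell over all genes tested, and 25 rose and 0 fell when adjusted over the list alone. Of 33 fibroblast and mesenchymal genes tested, 0 rose and 14 fell over all genes tested, and 1 rose and 26 fell when adjusted over the list alone. The median rho with the day was 0.902 for the naive list and -0.833 for the fibroblast list, the 100th and the 0th percentile of 10000 random lists of the same size and like covered length. Ribosomal protein and olfactory receptor genes, the controls, also rose under this scaling, as given further below. With the covered length left undivided, the naive list had 2 rises and 1 fall over all genes and 15 rises and 1 fall adjusted over the list alone (median rho 0.784), and the fibroblast list 17 falls over all genes and 31 adjusted over the list alone (median rho -0.905). Without day 8, 2 naive genes rose and 2 fibroblast genes fell over all genes, and 15 and 27 adjusted over the list alone. With peaks resized to 1000 bp, 0 passed over all genes, and 10 naive genes rose and 17 fibroblast genes fell adjusted over the list alone. Without days 1 and 2 these were 0, 14 and 10. With a score of 100 or more, 15 naive genes rose and 13 fibroblast genes fell over all genes.

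Sox2, a core pluripotency factor on chromosome 3 from 34649995 to 34652461 (mm10), had 1.38 kb covered on day 1, 14.01 kb on day 7 and 8.82 kb on day 8. Its rho of 1.00 had the smallest exact permutation p that 8 days allow (5.0e-05, adjusted p = 0.0105). Tdgf1, a Nodal co-receptor of early embryos on chromosome 9 from 110939608 to 110946158, rose from 0 kb on day 1 to 15.3 kb on day 7 and 11.04 kb on day 8 (rho = 0.98). Utf1 had 10.1 kb on day 7 and 4.99 kb on day 8, and Dppa3 rose from 0 kb to 7.98 kb and 1.83 kb from day 1 to days 7 and 8. Nanog rose from 3.09 kb to 19.4 kb and 11.6 kb (rho = 0.93). Esrrb (0 kb, 58.1 kb and 30.5 kb) and Pou5f1, which encodes Oct4 (0 kb, 19.7 kb and 15.5 kb), did not pass the threshold over all genes, with adjusted exact p of 0.0517 and 0.219. Klf4 had 12.5 kb on day 1, 5.14 kb on day 7 and 2.05 kb on day 8 (rho = -0.69, adjusted exact p = 0.165). Sox2, Pou5f1, Klf4 and Myc have transgene copies that share exon sequence with the genes themselves.

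Among the fibroblast genes, Prrx1, a mesenchymal transcription factor on chromosome 1 from 163245119 to 163315145, fell from 53.5 kb on day 1 to 5.06 kb on day 7 and 1.48 kb on day 8 (rho = -1). Cdh2, which encodes N-cadherin, fell from 21.4 kb to 0 kb on days 7 and 8, Fbln5 from 16.4 kb to 3.18 kb and 0.428 kb, and Lum from 9.05 kb to 3.04 kb and 0.527 kb. Col1a1 had 32.9 kb, 5.10 kb and 2.18 kb and did not pass over all genes (adjusted exact p = 0.111). Elovl6, a fatty acid elongase, had the largest rise past the threshold, from 11.8 kb on day 1 to 96.4 kb on day 7 and 42.1 kb on day 8. Slc25a13, Pigl, Ncor1, Fbxo36, Bicral, Hunk, Mybl2, Dlgap1 and Tbl1xr1 followed in this order. Lpp fell from 127 kb to 11.6 kb and 3.48 kb, and Dnm3, Igf1r, Fndc3b, Rbms1, Camk2d, Fbn1, Akap13, Rbms3 and Cacna1c followed among the falls.

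Epithelial genes rose at 5 of 22 and fell at 0 (7 rose adjusted over the list alone), while 0 rose with the undivided length, where the median rho was 0.131 against 0.548. Among them were Spint1, Cdh1, Epcam and Cldn4. Cdh1, which encodes E-cadherin, had 7.75 kb on day 1, 42.9 kb on day 7 and 24.4 kb on day 8. Hox genes fell at 6 of 33 and rose at 0 (25 fell adjusted over the list alone), and at 11 with the undivided length. Without day 8, 1 fell over all genes and 1 adjusted over the list alone, with a score of 100 or more 0 and 19, with peaks resized 0 and 1, and without days 1 and 2, 0 and 0. Hoxb5 went from 15.1 kb on day 1 to 0 kb on days 7 and 8, and Hoxd4 from 5.68 kb to 0 kb, and Hoxb7 and Hoxb8 also fell. Of 14 immediate early genes, Egr1 and Fosl1 fell and Ier2 rose (the same counts adjusted over the list alone), and with the undivided length 4 fell and 0 rose. Of 16 imprinted genes, Snrpn rose and Igf2r, Mest and Dlk1 fell (1 rose and 4 fell adjusted over the list alone), against 1 rise and 2 falls undivided.

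Ribosome biogenesis genes rose at 4 of 29 (Polr1b, Pes1, Nop58 and Dkc1; 3 adjusted over the list alone), and the median rho of 0.286 turned to -0.143 with the undivided length, where 0 rose. Of 20 cell cycle genes, Mcm6 and Bub1 rose (1 adjusted over the list alone), and 0 rose undivided, with the median rho turning from 0.369 to -0.0238. Of 12 germline genes, Sycp1 and Sycp3 rose (2 adjusted over the list alone) while the median rho of the list was -0.107, and 0 rose undivided. Of 13 NuRD complex genes, Rbbp7 rose (0 adjusted over the list alone), and 0 rose undivided, with the median rho turning from 0.452 to -0.0476. None of the 17 lineage transcription factor genes, 5 cell cycle inhibitor genes and 1 gene of the 2-cell stage tested passed, over all genes or adjusted over the list alone. With the undivided length 1 cell cycle inhibitor gene fell over all genes and 3 adjusted over the list alone.

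Markers of other cell types moved at few genes. Among keratinocyte markers Dsc3 fell (1 of 8), among blood markers Cd34 (1 of 8), among endothelial markers Erg (1 of 7) and among muscle and fat markers Pparg (1 of 4), with 1 fall each also adjusted over the list alone and with the undivided length. Of 10 neuron and glia markers Elavl4 rose and Map2 fell (the same adjusted over the list alone), against 0 rises and 2 falls undivided, with the median rho turning from 0.228 to -0.0126. Of 6 extraembryonic markers Tfap2c rose and Elf5 fell (1 rose and 2 fell adjusted over the list alone), and 0 passed undivided.

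Negative controls also rose under this scaling. Ribosomal protein genes rose at 7 of 22 (10 adjusted over the list alone), and olfactory receptor genes, taken here as silent in these cell types, at 46 of 138 tested (64 rose and 4 fell adjusted over the list alone). With the undivided length 0 ribosomal protein genes rose, the median rho falling from 0.726 to 0.119, and 0 olfactory receptor genes rose and 1 fell, with a median rho of 0.761. The whole list covered 118 Mb on day 1, 129 Mb on day 7 and 45.4 Mb on day 8. Without day 8 the median rho was 0.778 for olfactory receptor and 0.661 for ribosomal protein genes, and why these controls rose was not tested.

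Over all 16565 genes tested, 2661 passed an adjusted exact p of 0.05, 1497 rising and 1164 falling (6040 at an unadjusted p under 0.05). With the undivided length 1610 passed, 51 rising and 1559 falling, and 2647 of the 2661 genes kept their sign. With peaks resized to 1000 bp, or without days 1 and 2, 0 passed (4207 and 3510 unadjusted), and without day 8, 172 passed. Of the 2661 genes, 2586, 2528 and 2546 kept their sign under these settings, in that order. Without day 8 the calls within lists were 2 naive, 2 fibroblast, 1 Hox and 1 ribosomal protein gene. With a score of 100 or more 0 keratinocyte and 0 blood markers passed, no muscle and fat marker could be tested, and 0 cell cycle genes rose and 1 fell. On simulated data 100% of 200 planted trends were recovered, with 6 false calls of 16565. Every planted trend rose in the exact order of the days, so its recovery was close to certain. This share therefore cannot be read as the power for weaker trends.

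PolII rose at naive pluripotency genes and fell at fibroblast genes. Its lists covered 30.6 Mb on day 1, 64.9 Mb on day 2, 9.68 Mb on day 7 and 14.9 Mb on day 8. Of 23 naive pluripotency genes tested, 6 rose and 0 fell (15 rose adjusted over the list alone, median rho 0.881), and of 35 fibroblast genes, 9 fell and 0 rose (23 fell adjusted over the list alone, median rho -0.878). Tdh, which encodes threonine dehydrogenase, rose from 0 kb covered on day 1 to 2.74 kb on day 7 and 8.93 kb on day 8. Fgf4 rose from 0 kb to 2.65 kb and 6.81 kb, and Sox2 from 0.816 kb to 2.05 kb and 6.42 kb, and L1td1 also rose. Cd44, a surface marker of fibroblasts, fell from 62.5 kb to 0 kb on days 7 and 8, and Prrx1 from 47.5 kb to 0.175 kb and 0 kb, and Col5a2 and Runx1 also fell. With the undivided length 0 genes of both lists passed over all genes, and 4 naive genes rose and 23 fibroblast genes fell adjusted over the list alone. Without days 7 and 8, 0 naive genes rose and 4 fibroblast genes fell adjusted over the list alone, and without day 1, 13 and 20.

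Elsewhere PolII rose at 2 of 20 epithelial genes, among them Cldn4 (4 adjusted over the list alone), where the median rho turned from 0.302 to -0.167 with the undivided length. It fell at 1 of 14 immediate early genes, Fosl1 (4 adjusted over the list alone), at 1 of 17 imprinted genes, Igf2 (4), and at 1 of 6 extraembryonic markers, Dab2 (2). It rose at 3 of 33 olfactory receptor genes (4 adjusted over the list alone), where the median rho turned from 0.0476 to -0.165. No gene passed over all genes among 25 Hox, 10 lineage transcription factor, 29 ribosome biogenesis, 20 cell cycle, 6 cell cycle inhibitor, 9 germline, 13 NuRD, 22 ribosomal protein, 2 keratinocyte, 8 neuron and glia, 5 blood, 6 endothelial and 1 muscle and fat gene, and none of the 2-cell genes could be tested. Adjusted over the list alone, 1 NuRD gene rose and 2 fell, and 1 keratinocyte gene rose. Over all 14770 genes, 469 passed, 189 rising and 280 falling (3233 unadjusted). Under each of 5 other settings 0 passed, with between 446 and 469 of the 469 keeping their sign. Those settings were the undivided length (1025 unadjusted), a score of 100 or more (2816), peaks resized to 1000 bp (2457), no day 1 (4144), and no days 7 and 8 (1505).

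The number of naive pluripotency genes with any H3K27ac peak within 10 kb went from 17 of 30 on day 1 to 30 on day 8, and of fibroblast genes from 35 of 35 to 25. The naive count rose with the day (r = 0.904, exact p = 0.00476, adjusted p = 0.0333; rho = 0.913, exact p = 0.00476, adjusted p = 0.0421), though r without days 1 and 8 was 0.869 (exact p = 0.05). The fibroblast count fell by r (r = -0.887, exact p = 0.00714, adjusted p = 0.0413) and not by rho (-0.843, exact p = 0.0127, adjusted p = 0.0681), and r was -0.959 without days 1 and 8 (exact p = 0.00556). All 22 ribosomal protein genes had a peak on every day. Olfactory receptor genes with a peak rose from 53 to 146 of 1106 (r = 0.929, exact p = 0.00129, adjusted p = 0.0234; rho = 0.929, adjusted p = 0.0416; r = 0.925 without days 1 and 8). PolII peaks went from 12 to 28 naive genes (r = 0.972, exact p = 0.000198, adjusted p = 0.0156; rho = 0.988, adjusted p = 0.0234; r = 0.937 without days 1 and 8) and from 35 to 19 fibroblast genes (r = -0.930, exact p = 0.00109, adjusted p = 0.0234; rho = -0.970, adjusted p = 0.0234; r = -0.961 without days 1 and 8). These relations belong to a family of 118.

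**Figure D2:**
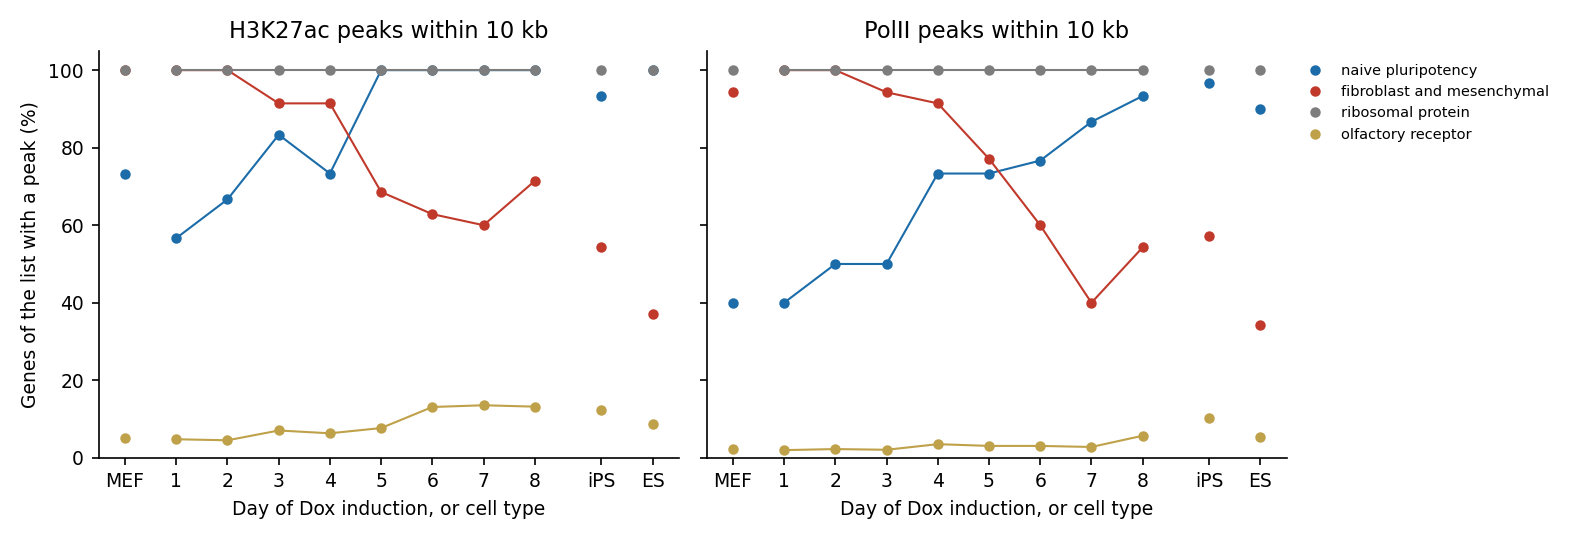
Percent of the genes of 4 lists with an H3K27ac peak (left) or a PolII peak (right) within 10 kb of the gene, by day of Dox induction or cell type in Mbd3f/- cells and V6.5 ES cells, 1 library per point. Naive pluripotency genes went from 17 to 30 of 30 for H3K27ac and fibroblast genes from 35 to 25 of 35, while olfactory receptor genes went from 53 to 146 of 1106; where ribosomal protein genes and another list are both at 100%, the points overlie each other.

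Oct4 and Sox2 left fibroblast regions and entered pluripotent regions during reprogramming. In fibroblast-only H3K27ac regions lay 16.2% of Oct4 peaks on day 1 and 4.72% on day 8, and 15.95% and 4.47% of Sox2 peaks, where chance gave 7.60% and 6.53% for Oct4 and 6.97% and 5.57% for Sox2. In pluripotent-only regions Oct4 peaks went from 4.00% to 19.9% and Sox2 peaks from 3.36% to 22.7%, against chance values of at most 1.80%. Klf4 peaks went from 3.99% to 12.3% and c-Myc peaks from 3.07% on day 1 to 9.16% on day 7 in pluripotent-only regions. In fibroblast-only regions Klf4 had 11.9% of its peaks on day 1 and 11.9% on day 8, and c-Myc 11.3% on day 1, 5.13% on day 3 and 9.60% on day 7.

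The 15 peak relations were tested as a family by exact two-sided permutation of the days. In fibroblast-only regions the share fell for Oct4 (r = -0.980, exact p = 9.92e-05, adjusted p = 0.000372; rho = -0.976; r = -0.978 without days 1 and 8) and Sox2 (r = -0.965, exact p = 0.000198, adjusted p = 0.000496; rho = -0.976; r = -0.960 without days 1 and 8). Klf4 (r = -0.422, exact p = 0.290; rho = -0.500, exact p = 0.216) and c-Myc (r = -0.358, exact p = 0.414; rho = -0.214, exact p = 0.662) did not pass. Without day 1 the r of Klf4 was -0.829 (adjusted exact p = 0.0345) and that of c-Myc turned to 0.0770. In pluripotent-only regions the share rose for Oct4 (r = 0.931, rho = 1.00) and Sox2 (r = 0.945, rho = 1.00), each with an exact p of 5.0e-05, the smallest possible, and an adjusted p of 0.000248. Without days 1 and 8 their r was 0.915 and 0.934. Klf4 (r = 0.939, exact p = 0.000347, adjusted p = 0.000744; rho = 0.929) and c-Myc (r = 0.958, exact p = 0.00119, adjusted p = 0.00223; rho = 0.964) also rose, with r of 0.967 (exact p = 0.00278) and 0.910 (exact p = 0.05) without the ends of the course. Among peaks with a score of 100 or more, Klf4 (r = 0.353) and c-Myc (r = 0.548) did not pass, with adjusted exact p of 0.436 and 0.284.

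**Figure D3:**
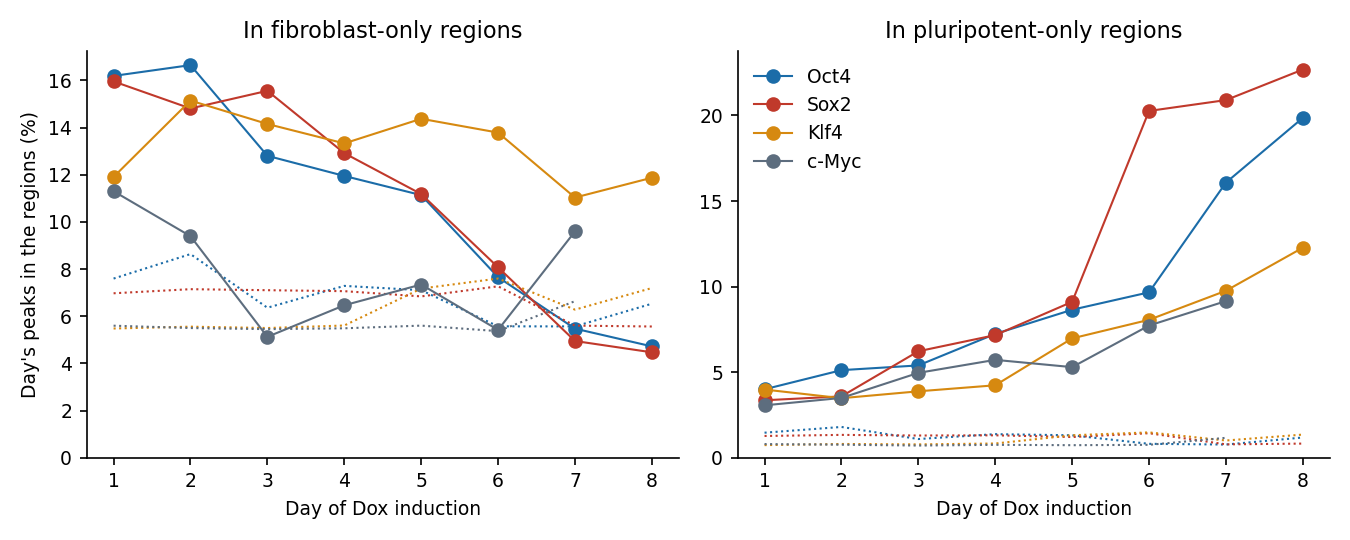
Percent of each day's Oct4, Sox2, Klf4 and c-Myc peaks that lie in fibroblast-only (left) or pluripotent-only (right) H3K27ac regions, by day of Dox induction in Mbd3f/- cells, 1 library per point; dotted lines give the share placed by chance. Oct4 went from 16.2% to 4.72% on the left and from 4.00% to 19.9% on the right, and the r of c-Myc on the left turned from -0.358 to 0.0770 without day 1.

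The share of a day's peaks found in the iPS list of the same target rose for Oct4, from 5.50% on day 1 to 29.7% on day 8 (chance at most 0.674%). It rose for Sox2 from 8.77% to 58.3%, for H3K27ac from 30.7% to 49.2% and for PolII from 44.6% to 80.9%. Chance was at most 5.28% for H3K27ac and 5.58% for PolII. With every peak resized to 200 bp, H3K27ac went from 13.9% to 33.6% and PolII from 26.6% to 42.9%. Klf4 had the opposite direction, from 44.7% of 4838 peaks on day 1 to 19.9% of 38553 on day 8, but from 44.7% to 70.0% when each day gave an equal number of its highest-scoring peaks and the iPS list stayed whole, and from 35.9% to 53.0% when the iPS list was shortened too. The equal number was the whole Klf4 list of day 1, so day 1 kept all its peaks. For c-Myc the share was 53.8% on day 1 and 36.8% on day 7, with an equal number of peaks per day 73.7% and 88.5%, and with the iPS list shortened too 49.3% and 59.5%.

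The rise passed for Oct4 (r = 0.909, exact p = 5.0e-05, the smallest possible, adjusted p = 0.000248; rho = 1.00; r = 0.883 without days 1 and 8) and Sox2 (r = 0.934, exact p = 0.000149, adjusted p = 0.000446; rho = 0.976; r = 0.932 without days 1 and 8). It passed for H3K27ac (r = 0.920, exact p = 0.00228, adjusted p = 0.00380; rho = 0.905; r = 0.927 without days 1 and 8). PolII passed (r = 0.868, exact p = 0.00521, adjusted p = 0.00781; rho = 0.833) but did not without days 1 and 8 (r = 0.719, exact p = 0.0972). Klf4 fell (r = -0.855, exact p = 0.0104, adjusted p = 0.0142; rho = -0.857), which also did not pass without days 1 and 8 (r = -0.705, exact p = 0.131), and turned to r = 0.861 (adjusted exact p = 0.00357) with an equal number of peaks per day, and to 0.821 (adjusted exact p = 0.00692) with the iPS list shortened too. The r of c-Myc was -0.608 (exact p = 0.134; rho = -0.393, exact p = 0.396), -0.792 without day 1 (adjusted exact p = 0.0451), 0.145 with an equal number of peaks per day (adjusted exact p = 0.767) and 0.262 with the iPS list shortened too (adjusted exact p = 0.600).

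The share of Oct4 peaks that overlapped both a Sox2 and a Klf4 peak of the day was 2.56% on day 1, 27.2% on day 5 and 21.6% on day 8. With an equal number of highest-scoring peaks it was 2.05%, 9.88% and 8.31% on these days, and with peaks resized to 200 bp 0.757%, 16.4% and 12.8%. Among sites bound by at least 1 of the 3 factors, the product of the Sox2 and Klf4 shares was 8.34%, 28.2% and 16.9% on these days. This product leaves out sites bound by none of them, so it is not a chance value over the genome. The relation with the day passed by r (0.793, exact p = 0.0234, adjusted p = 0.0292) and not by rho (0.571, exact p = 0.151), and r was 0.752 without days 1 and 8 (exact p = 0.100). It did not pass without day 1 (r = 0.671), day 2 (0.747), day 3 (0.780) or day 6 (0.779), nor under a stricter rule of overlap than 1 bp (r = 0.615, adjusted exact p = 0.127).

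At the naive pluripotency genes, Sox2 had a peak within 10 kb of 13 of 30 on day 1 and 28 on day 8 (r = 0.902, exact p = 0.00278, adjusted p = 0.0319; rho = 0.898, adjusted p = 0.0421; r = 0.857 without days 1 and 8). Klf4 went from 3 to 30 naive genes (r = 0.945, adjusted exact p = 0.0156; rho = 0.929, adjusted p = 0.0416; r = 0.899 without days 1 and 8), as the share of all genes with a Klf4 peak went from 19.4% to 70.3%, and ribosomal protein genes from 4 to 21 of 22. Oct4 went from 9 to 20 naive genes and from 21 to 11 fibroblast genes, and both r had an adjusted exact p of 0.0819. Oct4 peaks became fewer at blood markers (from 4 to 0 of 12, r = -0.942, adjusted exact p = 0.0234), imprinted genes (13 to 6 of 18, r = -0.891, adjusted p = 0.0333) and immediate early genes (11 to 5 of 14, r = -0.875, adjusted p = 0.0413), as the share of all genes went from 42.6% to 24.9%. Sox2 peaks became fewer at germline genes (7 to 1 of 16, r = -0.963, adjusted exact p = 0.0156) and muscle and fat markers (2 to 0 of 8, r = -0.943, adjusted p = 0.0324), as the share of all genes went from 36.5% to 24.3%. Klf4 counts also rose at ribosomal protein, olfactory receptor, cell cycle, keratinocyte and lineage transcription factor genes by r and rho, and at immediate early, ribosome biogenesis and germline genes by r alone (adjusted exact p between 0.0234 and 0.0415 for r). H3K27ac counts rose at 2-cell genes (0 to 5 of 9, r = 0.841, adjusted exact p = 0.0324) and, by r alone, epithelial genes (15 to 21 of 22, r = 0.852, adjusted p = 0.0333), as the share of all genes went from 70.5% to 69.0%. Without days 1 and 8 neither passed (r = 0.781 and 0.794, exact p = 0.0667 and 0.1). Nor did Oct4 at imprinted genes (r = -0.814, exact p = 0.0722). The further Klf4 relations did not pass without them either (r between 0.667 and 0.828, exact p between 0.0667 and 0.167), other than olfactory receptor genes (exact p = 0.0306). c-Myc had a peak at 3 naive genes on day 1 and 21 on day 7, when the share of all genes was 25.2% and 52.5%.

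The highest-scoring Oct4 peak at a naive gene on day 8 lay 928 bp outside Sox2 (chromosome 3, 34653389 to 34654639, score 1168), and Oct4 had a peak near Sox2 on all 8 days. It had its earliest peaks near Utf1, Dppa3 and Dppa5a on day 5, and near Nanog on day 3, where the day 8 peak lay on chromosome 6 from 122706899 to 122707991 (score 266). Gdf3, Fbxo15 and Tdh also had Oct4 peaks on day 8. Among fibroblast genes, Oct4 peaks lay at Ccn2, Lum, Fn1, Pdgfrb, Tagln, Snai1, Col3a1 and Pdgfra. Sox2 bound 171 bp outside Pou5f1 on day 8 (chromosome 17, 35503347 to 35505861, score 2979), and at Sox2, Dppa3, Klf2, Esrrb, Utf1, Nr5a2 and Dppa5a, and at the fibroblast genes Col3a1, Pdgfrb, Fn1, Ccn2, Col1a1, Snai1, Cd44 and Col5a1. Klf4 peaks on day 8 lay at Fbxo15 (chromosome 18, 84933651 to 84935557, score 1028), Pou5f1, Tdgf1, Nr5a2, Tbx3, Prdm14, Klf5 and Nanog, and at the fibroblast genes Vim, Col6a1, Snai1, Col1a1, Fn1, Runx1, Col6a2 and Col5a1. c-Myc peaks on day 7 lay at Gdf3, Tdh, Utf1, L1td1, Esrrb, Sox2, Fbxo15 and Klf4, and at Snai1, Runx1, Zeb1, Ccn1, Tagln, Col1a1, Fn1 and Prrx1.

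At promoters, H3K27ac rose over the 8 days at 6552 windows and fell at 6859, of 66128 tested. A window is 1000 bp around the start of a transcript, and several windows can belong to a gene. The largest rise among windows that kept their sign without each day was at ENSMUST00000113667 (slope 0.86 ± 0.0856 log2 per day, SE, n = 8 days), from 0.220 mean reads per base on day 1 to 14.2 on day 8. The largest fall was at ENSMUST00000123439 (-0.74 ± 0.0759), from 18.9 to 0.0630. H3K4me3, a mark of promoters, rose at 7945 and fell at 7871 windows, and H3K27me3, a mark of Polycomb repression, rose at 7267 and fell at 5446.

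H3K4me1, a mark of enhancers, rose at 4073 and fell at 3767 windows. H3K36me3, a mark of transcribed gene bodies, rose at 797 and fell at 879. The repressive marks H3K9me2 and H3K9me3 rose at 339 and 1313 windows and fell at 981 and 1253. Median slopes of the windows that rose were between 0.12 log2 per day (H3K4me3) and 0.37 (H3K9me3), and of those that fell between -0.12 (H3K4me3) and -0.31 (H3K36me3 and H3K9me3). None of 100 other orders of the days called as many windows for any mark. The highest was 7543 against 13411 for H3K27ac, 9796 against 15816 for H3K4me3, 4754 against 7840 for H3K4me1, 1236 against 1676 for H3K36me3, 8847 against 12713 for H3K27me3, 671 against 1320 for H3K9me2 and 1348 against 2566 for H3K9me3.

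Among windows where H3K27ac rose, the slope was upward in 84.4% of 6422 for H3K4me3, 19.5% of 4464 for H3K27me3 and 56.7% of 6093 for H3K4me1. Among windows where H3K27ac fell, it was downward in 82.5% of 6410, 16.1% of 6187 and 50.2% of 6495. These shares cover windows with a slope for both marks and count the sign of the second slope alone. Slopes were correlated across windows at rho = 0.54 for H3K27ac with H3K4me3, -0.51 for H3K27ac with H3K27me3, 0.43 for H3K27me3 with H3K9me3 and 0.40 for H3K9me2 with H3K9me3, and windows are not independent replicates. Gatad2a-/- cells had the sign of Mbd3f/- cells at 94.3% of the rising and 94.6% of the falling H3K27ac windows. Their own slope over days 2, 4, 6 and 8 was called at 5277 windows, 2228 rising and 3049 falling (14525 unadjusted).

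The split between rises and falls depends on the scaling, since quantile normalization removes any global change of a mark. Rising windows made up 48.9% of calls for H3K27ac, 50.2% for H3K4me3, 52.0% for H3K4me1, 47.6% for H3K36me3, 57.2% for H3K27me3, 25.7% for H3K9me2 and 51.2% for H3K9me3. With no rescaling they made up, in that order, 4.70%, 29.7%, 0.843%, 11.4%, 72.0%, 6.97% and 72.1%, and with median centring 34.7%, 27.5%, 40.2%, 32.9%, 44.2%, 34.4% and 37.3%. The median of all slopes moved with no rescaling to -0.16 log2 per day for H3K27ac and -0.19 for H3K4me1. On simulated data a slope of 0.4 log2 per day was recovered at 77% of windows for H3K27ac, 97% for H3K4me3, 69% for H3K4me1, 57% for H3K9me2, 16% for H3K36me3, 8% for H3K27me3 and 3% for H3K9me3. For H3K27me3 the real fit called 12713 windows, with a median slope of 0.35 log2 per day among the rises. The simulated shares therefore cannot be read as the power of the real fits.

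Single days carried many of these calls. The H3K27ac count was 8625 without day 1 and 7970 without day 7, and 5101 without the libraries of days 1 and 2, which show no ceiling on duplicate reads. The H3K4me1 count was 4877 without day 1. H3K36me3 had 952, 1091 and 975 calls without day 2, 7 and 8. H3K9me2 had 856, 391, 591, 593 and 432 without day 1, 2, 3, 7 and 8, and H3K9me3 had 1703, 1039, 974 and 1275 without day 1, 2, 7 and 8.

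The promoter profile of all 7 marks became more like that of iPS cells and less like that of MEFs. Likeness was the Spearman correlation across promoter windows with the iPS library of the mark minus that with the MEF library. It went from -0.123 on day 1 to 0.182 on day 8 for H3K27ac, from -0.0271 to 0.0879 for H3K4me3, from -0.173 to 0.252 for H3K4me1 and from -0.272 to 0.260 for H3K27me3. It went from -0.0908 to 0.0808 for H3K9me2, from -0.433 to 0.0535 for H3K9me3, and from -0.336 to -0.0890 for H3K36me3, which stayed closer to MEFs and where ES cells had 0.00268. H3K27ac likeness was -0.196 in Gatad2a-/- MEFs, -0.0326 on day 4 and 0.185 on day 8, and in WT cells -0.297 in MEFs, -0.128 on day 4, -0.0800 on day 8 and 0.152 as iPS cells. The H3K27ac MEF reference came from the same earlier series as the WT libraries. The WT values may therefore lean toward MEFs by series, which was not tested. ES cells had 0.261 for H3K27ac. For some marks the highest bin or the duplicate ceiling went with stage. The highest H3K9me3 bin was 5014 in MEFs, 10028 on day 4, and 15135 on day 5 and in iPS cells. H3K27me3 lacked a duplicate ceiling in MEFs and on days 1 and 2, but not on day 3 or in iPS cells. The highest H3K9me2 bin was 10237 in MEFs and 10280 in iPS cells. How far these features bear on likeness was not tested for the MEF and iPS references.

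The relation with the day passed for each of the 7 marks, a family of 7. H3K4me3 (r = 0.994), H3K27me3 (r = 0.971), H3K9me2 (r = 0.996) and H3K9me3 (r = 0.977) each had rho = 1.00 and an exact p of 5.0e-05, the smallest possible, with an adjusted p of 8.68e-05. H3K27ac had r = 0.964 (exact p = 0.000198, adjusted p = 0.000231; rho = 0.952, exact p = 0.00114), H3K36me3 r = 0.985 (exact p = 9.92e-05, adjusted p = 0.000139; rho = 0.976, exact p = 0.000397) and H3K4me1 r = 0.871 (exact p = 0.00640, adjusted p = 0.00640; rho = 0.810, exact p = 0.0218). By rho H3K4me1 did not pass without day 1 or without day 2 (0.75 each, exact p = 0.0663). Without days 1 and 8, r lay between 0.852 for H3K4me1 and 0.998 for H3K9me2.

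**Figure D4:**
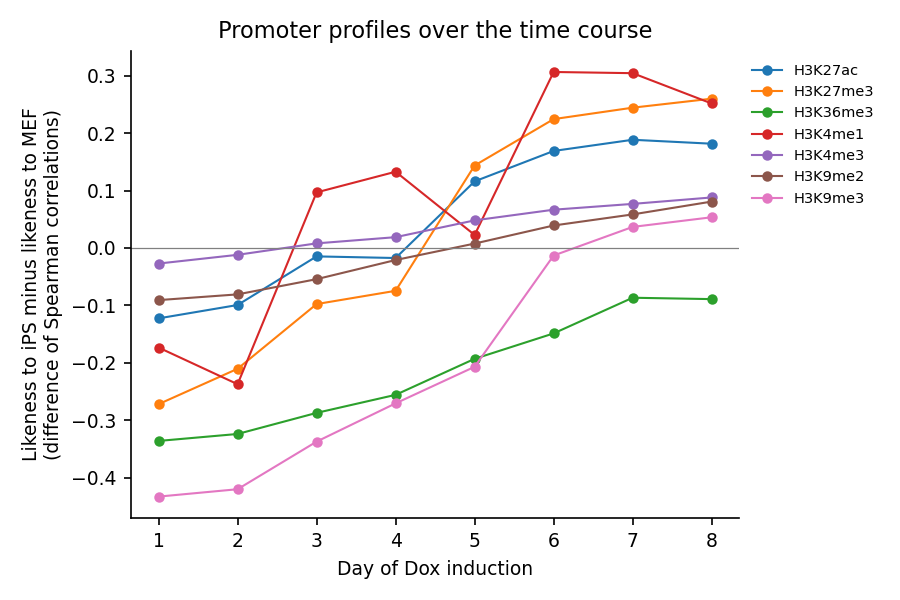
Likeness of the promoter profile to iPS cells minus likeness to MEFs (difference of Spearman correlations across promoter windows), by day of Dox induction in Mbd3f/- cells, 1 line per histone mark and 1 library per point. H3K27ac went from -0.123 on day 1 to 0.182 on day 8, and H3K36me3 from -0.336 to -0.0890, staying below 0.

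H3K27ac at promoters was compared between genotypes at matched stages, in limma fits with the stage as a block. Mbd3f/- and WT cells differed at 45 of 66128 windows over 4 matched stages (MEF, days 4 and 8, iPS), 19 higher and 26 lower in Mbd3f/- cells (10430 at an unadjusted p under 0.05). Gatad2a-/- and Mbd3f/- cells differed at 209 windows over 5 stages (MEF, days 2, 4, 6 and 8), 47 higher and 162 lower in Gatad2a-/- cells (7538 unadjusted). Gatad2a-/- and WT cells differed at 2513 windows over 3 stages (MEF, days 4 and 8), 720 higher and 1793 lower in Gatad2a-/- cells (13108 unadjusted). The slope over days 2, 4, 6 and 8 differed between Gatad2a-/- and Mbd3f/- cells at 0 windows by limma (3028 unadjusted).

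These counts rest on single stages and on the scaling. The Mbd3f/- to WT count was 0 without day 4, 0 without day 8, 11 without iPS cells and 521 without MEFs. That of Gatad2a-/- to Mbd3f/- was 76, 15, 18 and 43 without day 2, 4, 6 and 8, and 1059 without MEFs, and that of Gatad2a-/- to WT 1090 and 4574 without day 4 and day 8, and 3994 without MEFs. With no rescaling the counts were 8968, 29773 and 32292, with 2.39%, 0.326% and 1.08% of them higher in the genotype named before the other, against 42.2%, 22.5% and 28.7% with quantile normalization. With median centring they were 76, 1642 and 11792, with 67.1%, 19.2% and 21.3% higher, and the slope differed at 45 windows. The median of all differences moved with no rescaling to -0.38, -0.60 and -0.66 log2. On simulated data a 2-log2 difference was recovered at 26%, 81% and 0% of windows in the 3 comparisons, and a slope difference of 0.8 log2 per day at 49%. The real fit of Gatad2a-/- against WT called 2513 windows, with a median absolute difference of 1.34 log2, where the simulation recovered 0%. These simulated shares therefore cannot be read as the power of the real fits. Genotype goes with series on days 4 and 8 and in iPS cells for Mbd3f/- against WT, at all 3 stages for Gatad2a-/- against WT, and in MEFs for Gatad2a-/- against Mbd3f/-. The source name of the Gatad2a-/- MEF library also calls it post induction, against its title.

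By H3K27ac peaks, naive pluripotency genes with a peak numbered 16 of 30 in WT and 22 in Mbd3f/- MEFs, 16 and 22 on day 4, 23 and 30 on day 8, and 30 and 28 in iPS cells. Fibroblast genes with a peak numbered 35 of 35 in both MEFs, 34 and 32 on day 4, 35 and 25 on day 8, and 14 and 19 in iPS cells. Olfactory receptor genes with a peak, the control taken as silent, numbered 44 of 1106 in WT and 58 in Mbd3f/- MEFs, 36 and 70 on day 4, 38 and 146 on day 8, and 68 and 136 in iPS cells. At the Mbd3 gene and 10 kb around it lay 5 peaks in WT and 4 in Mbd3f/- MEFs, and 3 and 12 on day 8, but on day 8 they covered 13.6 kb in WT and 5.05 kb in Mbd3f/- cells. At Gatad2a lay 9 and 10 in MEFs and 8 and 25 on day 8, which covered 25.9 kb in WT and 15.8 kb in Mbd3f/- cells on day 8. The WT list of day 8 had 34461 peaks of median width 2442 bp and the Mbd3f/- list 85348 of 281 bp, with 51.3% of Mbd3f/- peaks in the WT list. These values come from 1 library each and were not tested.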

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

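In this part the Klf4 tests, the counts of peaks before induction, the H3K4me1 comparison, the Oct4 test with the iPS list left whole and the splits within stages were chosen only after the result was seen, and the other tests were set before it, when library depths and peak widths were already known.

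Klf4 and c-Myc peaks in MEFs before induction drew attention as a signal in libraries outside the day comparisons. Klf4 had 7045 peaks, of which 21.3% lay in fibroblast-only and 1.45% in pluripotent-only H3K27ac regions, and 48.3% of its day 1 peaks lay in the MEF list. c-Myc had 8538 peaks, of which 16.5% and 1.15% lay in these regions, and 74.4% of its day 1 peaks lay in the MEF list. Median peak width was 1091 bp in MEFs and 161 bp on day 1 for Klf4, and 1320 bp and 203 bp for c-Myc. No chance share was computed for these overlaps. Pluripotent-only regions leave out MEF H3K27ac peaks by definition, which bears on the low shares there. No group of 4 to 10 like samples was there to test for a sample far from the others.

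The H3K27ac promoter trends of Mbd3f/- cells were weighed against duplicate handling and depth. The libraries of days 1 and 2 show no ceiling on duplicates, whereas the Gatad2a-/- libraries all do, yet the called windows had the same sign in Gatad2a-/- cells in 94.3% of cases, the lower of the shares for rises and falls, which argues against duplicates as the whole cause, though only 5101 windows were called without these libraries. H3K27ac depth was 8.04 on day 1, 5.77 on day 2, 3.33 on day 3, 3.67 on day 7 and 2.36 on day 8. The high values of days 1 and 2 may include duplicates, so these libraries do not tell depth from duplicates. H3K4me3 depth was 10.32 on day 1, also without a ceiling, 13.04 on day 4 and 5.18 on day 8. The lower share with the same sign in H3K4me3 was 82.5%, which argues against depth as the whole cause. In H3K4me1, whose depth was 2.44 on day 1, 3.12 on day 4 and 0.482 on day 8, 56.7% of the rises and 50.2% of the falls had the same sign. The H3K4me1 libraries of days 1 and 4 show no ceiling on duplicates, so their depths may include duplicates. The H3K4me1 comparison therefore cannot decide on depth. Depth as a part of the cause stays open, since H3K4me3 depth was also lowest on day 8. Reprogramming itself also stays open, untested, as does the global level of the mark, which quantile normalization removes.

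The rising share of Oct4 peaks found in iPS cells was weighed against peak width and list length. With an equal number of highest-scoring peaks per day the r was 0.923, and with the iPS list shortened to that number too 0.925, against 0.909 as reported. List length alone therefore does not account for the rise. With all peaks resized to 200 bp the r was 0.912. Oct4 peaks had a median width of 1401 bp on day 1 and 207 bp on day 7. Resizing took the share from 5.50% to 3.71% on day 1 and from 29.3% to 28.0% on day 7. It can thus itself favour a rise, and it cannot decide on peak width. Width and length were not held equal together. The antibody of the iPS library differs from that of the time course, which cannot make the days differ. A move of Oct4 to sites bound in iPS cells is a candidate explanation, as a hypothesis.

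The falling share of Klf4 peaks found in iPS cells may follow from list length. With an equal number of highest-scoring peaks per day and the iPS list left whole, the r turned from -0.855 to 0.861, as it would if the longer late lists added weaker peaks. That number was 4838, the whole day 1 list. The share was then 44.7% on day 1, 55.7% on day 2, 63.2% on day 6, 57.8% on day 7 and 70.0% on day 8. The turned r was not computed without days 1 and 8, so how far it leans on them is open. With the iPS list shortened to that number too the r was 0.821. With peaks resized to 200 bp the r was -0.846. Klf4 peaks had a median width of 198 bp on day 3 and 1378 bp on day 6. Resizing took the share from 38.4% to 33.7% on day 3 and from 22.6% to 15.9% on day 6. Resizing can thus itself favour a fall, and it cannot decide on peak width, which stays open. Since list length may account for the fall, a loss of iPS sites by Klf4 is not needed for it.

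For the genotype comparisons, other splits of the same libraries were counted. For Mbd3f/- against WT, 3 of 35 splits gave as many windows, so chance cannot be excluded: the real count was 45 and the highest other 354, and 3 splits could not be fitted. For Gatad2a-/- against Mbd3f/-, 7 of 100 splits gave as many, so chance cannot be excluded, with a real count of 209 and a highest other of 2176. In both comparisons a split called several times the real count, which points to a structure of the samples whose cause was not tested; these splits set apart the libraries of 2 of 4 and 1 of 5 stages. Of splits that keep 1 library of each stage in each group, 1 of 8 and 1 of 16 gave as many, with a highest other of 0, and these are too few for a share under 0.05. For Gatad2a-/- against WT the 10 splits are too few for a share under 0.05, with 1 of 10 as large, a real count of 2513 and a highest other of 0. For the difference in slope the real count was 0, which every split reaches (35 of 35, highest other 5), so the splits say nothing about it.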

How the results depend on the processing

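The settings named as 62-base reads, duplicate ceiling, resized peaks, equal number of peaks and all gene settings were chosen only after the data were seen. By r, likeness kept its direction and its side of the threshold in all 56 fits that leave out a day and all 30 others, while by rho H3K4me1 did not pass without day 1 or day 2 (0.75 each, exact p = 0.0663). Peak relations did so by r in 109 of 117 and 64 of 72, promoter trend counts stayed within 1.5 times in 41 of 56 and 38 of 63, genotype counts in 0 of 12 and 10 of 25, and gene counts in 1 of 10. The cause was not tested for any change below.

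Trend counts without each day ran from 7970 to 13858 for H3K27ac, 11015 to 15356 for H3K4me3, 4877 to 7953 for H3K4me1, 952 to 1785 for H3K36me3, 8972 to 13074 for H3K27me3, 391 to 1819 for H3K9me2 and 974 to 2846 for H3K9me3. With the highest bin they were 8722, 8126, 3278, 22, 5745, 87 and 78, and with a step between days 3 and 4 they were 2231, 3791, 2683, 75, 6605, 63 and 404, in that order. With no rescaling 25637 were called for H3K27ac, 5094 for H3K4me3, 8443 for H3K27me3, 674 for H3K9me2 and 1346 for H3K9me3. Median centring gave 7615 for H3K4me3, and the MEF library as day 0 gave 3851 for H3K9me3. Without the libraries that lack a duplicate ceiling H3K27ac had 5101, and libraries of 62-base reads gave 8489 for H3K27ac, 6408 for H3K4me3 and 7727 for H3K27me3.

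Genotype counts without each stage ran from 0 to 521 for Mbd3f/- against WT, 15 to 1059 for Gatad2a-/- against Mbd3f/- and 1090 to 4574 for Gatad2a-/- against WT. No rescaling gave 8968, 29773 and 32292, median centring 76, 1642 and 11792 (and 45 for the difference in slope), and no stage block 0, 0 and 0. For Mbd3f/- against WT the median as pseudocount gave 29, the lowest 50% left out 29 and the highest bin 68. The lowest 50% left out gave 72 for Gatad2a-/- against Mbd3f/-, and the highest bin 1317 for Gatad2a-/- against WT.

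With an equal number of peaks per day the r turned for the shares of Klf4 (0.861) and c-Myc (0.145) found in iPS cells (0.821 and 0.262 with the iPS list shortened too), and passed for c-Myc in fibroblast-only regions (-0.862). With a score of 100 or more, Klf4 (0.353) and c-Myc (0.548) in pluripotent-only regions no longer passed, nor did the overlap of Oct4, Sox2 and Klf4 under the stricter rule (0.615). Without each day, r ran from -0.922 to -0.777 for Klf4 and -0.792 to -0.139 for c-Myc found in iPS cells, -0.829 to -0.237 for Klf4 and -0.758 to 0.0770 for c-Myc in fibroblast-only regions (above 0 without day 1), and 0.671 to 0.855 for the overlap of the 3 factors. By rho the share found in iPS cells did not pass for PolII without day 1, 6, 7 or 8 (0.75 each), with a score of 100 or more (0.714) or an equal number of peaks per day (0.738, and 0.599 with the iPS list shortened too), nor for Klf4 without day 1, 2, 3 or 8 (-0.786 each). By rho Klf4 in pluripotent-only regions did not pass under the stricter overlap (0.762), and the overlap of the 3 factors passed with a score of 100 or more (0.952) and an equal number of peaks (0.762).

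The H3K27ac gene count was 1610 with the undivided length, 0 with peaks resized to 1000 bp, 0 without days 1 and 2 and 172 without day 8. The PolII gene count was 0 with the undivided length, 0 with a score of 100 or more, 0 with peaks resized, 0 without day 1 and 0 without days 7 and 8.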

Other observations

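The windows in this part were chosen only after their values were seen, and no explanation was tested for them.

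At 8 promoter windows, H3K9me3, H3K9me2 and H3K36me3 all appeared between days 2 and 3 and stayed. The criterion was at least 1 mean read per base and a 4-fold gain in all 3 marks, and 0 windows met the reverse. Median H3K9me3 coverage at these windows was 0.150 reads per base on day 1, 2.84 on day 3, 6.70 on day 8, 6.96 in iPS cells and 1.41 in ES cells. Median H3K9me2 coverage was 0.432 on day 1, 5.03 on day 3 and 4.91 on day 8. Median H3K36me3 coverage was 0.142 on day 1, 3.11 on day 3, 2.42 in iPS cells and 0.776 in ES cells. The cells had grown on irradiated human fibroblasts from day 3, per the labels.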
